A study of Rattus norvegicus with 56 samples.

How the data were processed

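RNA was sequenced from tubule segments microdissected from the kidneys of male Sprague-Dawley rats whose left ureter had been ligated (unilateral ureteral obstruction, UUO) or only exposed (sham). The segments were the cortical collecting duct (CCD) and the cortical thick ascending limb (cTAL), each taken at 30 min and at 3 h. Each arm at each time held 4 numbered replicates, with 2 libraries per number for CCD and 1 library per number for cTAL, so 48 libraries were used, 24 at each time. The series also lists 8 whole-kidney samples, which had no values among the tables used and were not analysed here. Libraries of the same arm, time and number were taken as one animal. The p-values of single genes and of the exact permutation tests below measure the spread between animals as they are numbered. The labels do not say more about which libraries share an animal.

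Per the labels' protocols, cDNA was made with a SMARTer V4 kit and libraries with Nextera XT. Per the submitters' processing notes, STAR 2.7.3 and RSEM 1.3.3 were used with the rat build Rnor_6.0. The deposited values are TPM per gene, that is transcripts scaled to a fixed total, with a separate table for each time. TPM keep no record of depth, so the depth of each library is unknown, and no interval or detection limit that needs it is given. As a measure of coverage, genes at 1 TPM or more numbered 8744 to 11916 per library at 30 min and 9585 to 10750 at 3 h. The protocols do not say that these libraries keep strand, so reads of a gene and of an antisense partner could not be told apart. The tables hold the same 32883 gene identifiers. Of these, 5174 are named differently between times, so genes were matched by identifier and printed under a single name. A symbol shared by several identifiers, as for 2795 of them, is printed with its count of loci where it matters. Levels were never compared between the tables, because each was made by itself.

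The TPM were analysed as log2(TPM + 1), and every log2 change below is on that scale, which understates the change of genes near 1 TPM. The 2 CCD libraries of a number were averaged on the log2 scale before testing. Genes with at least 1 TPM in at least 4 of the 8 replicates of a comparison were tested with limma 3.58.1 in R 4.3.3 (moderated linear model with a mean-variance trend). Benjamini-Hochberg adjustment ran over the genes tested, and genes with an adjusted p under 0.05 were called. The 4 main comparisons set UUO against sham in each segment at each time, 4 replicates against 4. Differences between segments were tested on CCD minus cTAL within each numbered animal, and differences between times on the change at 3 h minus the change at 30 min. Segment identity was tested on CCD minus cTAL within the sham animals. Aqp2 was also tested with a two-sided exact permutation test of the mean log2 value, whose smallest possible p with 4 against 4 is 0.0286. Tables were read with the data.table package, version 1.17.8, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

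Gene lists, the tests of the comparisons, the alternatives listed below and the rule for naming genes were chosen before the data were examined, and settings added later are named as such. The 23 pathway lists cover principal cell water and sodium transport, transcription factors described as regulators of Aqp2, AP-1 factors, other immediate early genes, MAP kinase feedback inhibitors, the NF-kB pathway, cytokines and chemokines, EGF family ligands and receptors, and epithelial injury markers. They further cover TGF-beta signalling and matrix, YAP targets, actin cytoskeleton, heat shock proteins, the unfolded protein and integrated stress response, NRF2 targets, hypoxia and glycolysis, prostaglandin synthesis, p53 targets, thick ascending limb transport, intercalated cell transport, junction proteins, mitochondrial metabolism and ribosomal proteins. Another 15 lists hold markers of cell types that the dissected tubules could contain. Each list was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of its kind. A list is said to be called where camera passed at the preset correlation. Camera compares a list with the other genes, whereas fry asks whether the list itself moves one way. At the preset correlation camera's p-values rest on that assumed correlation between genes and do not measure the spread between animals. The count of called members is over all genes tested, and the count adjusted over the list alone is beside it.

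Named genes were, for each comparison, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 TPM in either arm and no overlap between arms. Up to 4 called members of each list were added, or the member with the smallest p where none was called. A fixed set of 18 genes was named whether called or not. Where fewer than 5 genes were called, the 5 with the smallest p were also named. Symbols that are only clone or locus names were counted but not named, and the few printed below were chosen after their values were seen. Aqp4, Fxyd4, Hsd11b2, Scnn1g and Slc34a1 in CCD at 3 h fall outside this rule and were also chosen after their values were seen. For differences between segments or times, the 5 genes with the smallest p in each direction were named. Identity was described with segment markers from the lists.

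Replicates of sham and UUO share their numbers, so the deviations of same-numbered replicates from their group means were correlated across genes. In CCD at 30 min the 4 correlations were 0.188, 0.148, 0.115 and 0.229, and 6 of the 8 replicates correlated best with their own number, so the numbers were taken to pair the samples there. That pairing comes from the data, since no label states a shared day or batch. With the number as a block, 3 genes were called there, as without it.

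Each test was checked on simulated data drawn around the real means and spreads, with 50 genes changed by each of several sizes. The changed genes were taken above a mean level of 5 TPM, and noise was drawn for each gene by itself. Recovery at lower levels, and false calls where genes are correlated, were therefore not measured. Of genes changed by 1 on the log2 scale, 30% were recovered in CCD at 30 min, 76% in CCD at 3 h, 52% in cTAL at 30 min and 54% in cTAL at 3 h. For a change of 2 the recovery was 80%, 86%, 88% and 84% in the same order. Unchanged genes made up 8.55%, 4.90%, 3.23% and 6.82% of the simulated calls in that order, and 8.85% for the time difference in CCD, so the share lay above 5% in some. Each share comes from a single simulated data set, so whether the 5% aim is exceeded on average was not measured. The alternatives tried were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-of-ratios rescaling, quantile normalization, and a log2 change of at least 1. Others were the replicate number as a block, a joint fit of all 4 groups of a time, each CCD library alone, all CCD libraries at once with a within-number correlation, and averaging TPM before the log. Robust moderation and weights per replicate were tried for the 4 main comparisons, and the segments as unpaired samples for the segment differences. Every comparison was also repeated without each replicate in turn.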

Results

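The study followed the first hours after ligation of a rat ureter in 2 microdissected tubule segments. CCD carries the principal cells, in which vasopressin controls water permeability through the water channel aquaporin-2 (Aqp2), and cTAL reabsorbs salt through the cotransporter Slc12a1 and secretes uromodulin (Umod). CCD and cTAL were sampled in 4 sham and 4 UUO replicates at 30 min and in as many at 3 h. All values are TPM per gene, and sequencing depth is unknown because TPM do not keep it. Values are mean ± SD over 4 replicates per arm unless stated, and SE is the standard error of a log2 change from limma.

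The sham samples first showed how far the 2 segments differ. Aqp2 stood at 4887 ± 941 TPM in CCD and 0.678 ± 0.825 TPM in cTAL at 30 min, and at 10204 ± 754 TPM and 91.4 ± 180 TPM at 3 h. The vasopressin receptor Avpr2 was also higher in CCD, with 492 against 44.6 TPM at 30 min and 765 against 66.4 TPM at 3 h. Umod was the reverse, with 129 TPM in CCD and 52190 TPM in cTAL at 30 min, and 2006 ± 2185 TPM and 41305 TPM at 3 h. Slc12a1 stood at 4.80 TPM in CCD and 2832 TPM in cTAL at 30 min, and at 24.3 and 370.1 TPM at 3 h. Slc26a4, the apical anion exchanger of type B intercalated cells, was at 797 TPM in CCD and 0.225 TPM in cTAL at 30 min. Within the sham animals, limma called 6482 of 11174 genes between the segments at 30 min, 4928 higher and 1554 lower in CCD. At 3 h it called 4121 of 9832 genes, 3035 higher and 1086 lower in CCD. The median of all genes lay at 0.31 at 30 min and 0.32 at 3 h on the log2 scale. Median-of-ratios rescaling gave 3155 higher and 2757 lower at 30 min, and 1635 higher and 1752 lower at 3 h. Quantile normalization gave 2944 higher and 3174 lower at 30 min, and 1619 higher and 1708 lower at 3 h. Of the 8 CCD sham libraries at 3 h 2 were above 5000 TPM of Umod, as was 1 UUO library, and 1 cTAL sham replicate at 3 h held 361 TPM of Aqp2.

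The first question was whether CCD had already responded after 30 min of obstruction. Aqp2 was at 3054 ± 1114 TPM in UUO and 4887 ± 941 TPM in sham, 1.73-fold lower, but this difference did not pass either test (log2 change -0.79, SE 0.29, adjusted p = 0.281, two-sided exact permutation p = 0.0571). Both tests ignore the numbered pairs, as do the other p-values of this paragraph. With the number as a block, exact permutation p for Aqp2 was 0.125, the smallest sign flips allow, so that test could not pass. Aqp3, the basolateral water channel, had a log2 change of -0.44 and Avpr2 one of -0.48, and neither passed (adjusted p = 0.417 and 0.420). Hsd11b2, the enzyme that keeps cortisol-type steroids off the mineralocorticoid receptor, was at 378 ± 45.6 TPM in UUO and 846 ± 138 TPM in sham with no overlap between arms, but its adjusted p was 0.181. The stress-induced cytokine Gdf15 had a log2 change of -2.84 (SE 0.75, adjusted p = 0.237). Among the early response factors, Fos had a log2 change of -0.39, Jun -1.25, Egr1 -1.13 and Atf3 0.23, none of which passed. Zfp771 and Vmac had the smallest p among genes that were not called, with log2 changes of -1.09 and -1.74 (adjusted p = 0.112 and 0.181).

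Only 3 of 11369 genes were called in CCD at 30 min, 1 higher and 2 lower, against 1789 with an unadjusted p under 0.05. Among all genes 8.76% had no overlap between the arms, where chance gives 2.86%, and with library 1 of each replicate alone 878 genes were called, 6 higher and 872 lower, but with library 2 alone 1 was. All 3 of the called genes are loci with clone or locus names only, and they were chosen for naming after their values were seen. AABR07007730.1 was at 24.8 ± 5.21 TPM in UUO and 0.210 ± 0.155 TPM in sham (log2 change 4.41, SE 0.20, adjusted p = 1.45e-05). AABR07051395.1 and RGD1560398 were listed at 0 in every CCD UUO library (adjusted p = 2.28e-04 and 0.0239), and the call of RGD1560398 was lost in 6 of 8 fits without 1 replicate. Both were also at 0 in library 2 of CCD sham replicate 2. In cTAL both were at 0 in every sham library, while AABR07051395.1 reached 7.51 TPM in UUO replicate 4 and RGD1560398 9.05 TPM in UUO replicate 2. The median of all genes was -0.31 on the log2 scale and -0.02 after median-of-ratios rescaling, with which the Aqp2 change became -0.42. The share of TPM from mitochondrially encoded genes was also higher in UUO, with medians of 20.0% and 14.7% per library.

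Against that general shift, 2 pathway lists stood higher in CCD at 30 min by camera, although none of their members was called. The 24 ribosomal protein genes had a median log2 change of 0.12 (adjusted p = 1.78e-14, and adjusted p = 0.608 with an estimated correlation). The 10 measured cytokines and chemokines had a median of 0.08 (adjusted p = 4.47e-04, and adjusted p = 0.608 with an estimated correlation). With the replicate number as a block, camera again called both (adjusted p = 1.2e-11 and 5.83e-04, and adjusted p = 0.987 each with an estimated correlation). Library 2 of UUO replicate 2, which had the fewest genes at 1 TPM or more, held 4.48% of its TPM in ribosomal protein genes. The median over the CCD UUO libraries was 2.38%. With UUO number 2 taken from its library 1 alone, chosen after seeing the data, the median log2 change of all genes was -0.17. The lists were not retested without that library. Proximal tubule markers, with a median of 0.27 over 7 genes, and macrophage markers, with a median of -0.09 over 7 genes, also stood higher than other genes by camera (adjusted p = 1.75e-04 and 0.0291, and adjusted p = 0.583 for both with an estimated correlation). For the macrophage list the median and the mean, -0.03, were below 0 while camera's direction was up, because the other genes lay lower still. In the principal cell transport list 0 of 14 measured members were called, with 0 higher and 1 lower when adjusted over the list alone.

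**Figure D1:**
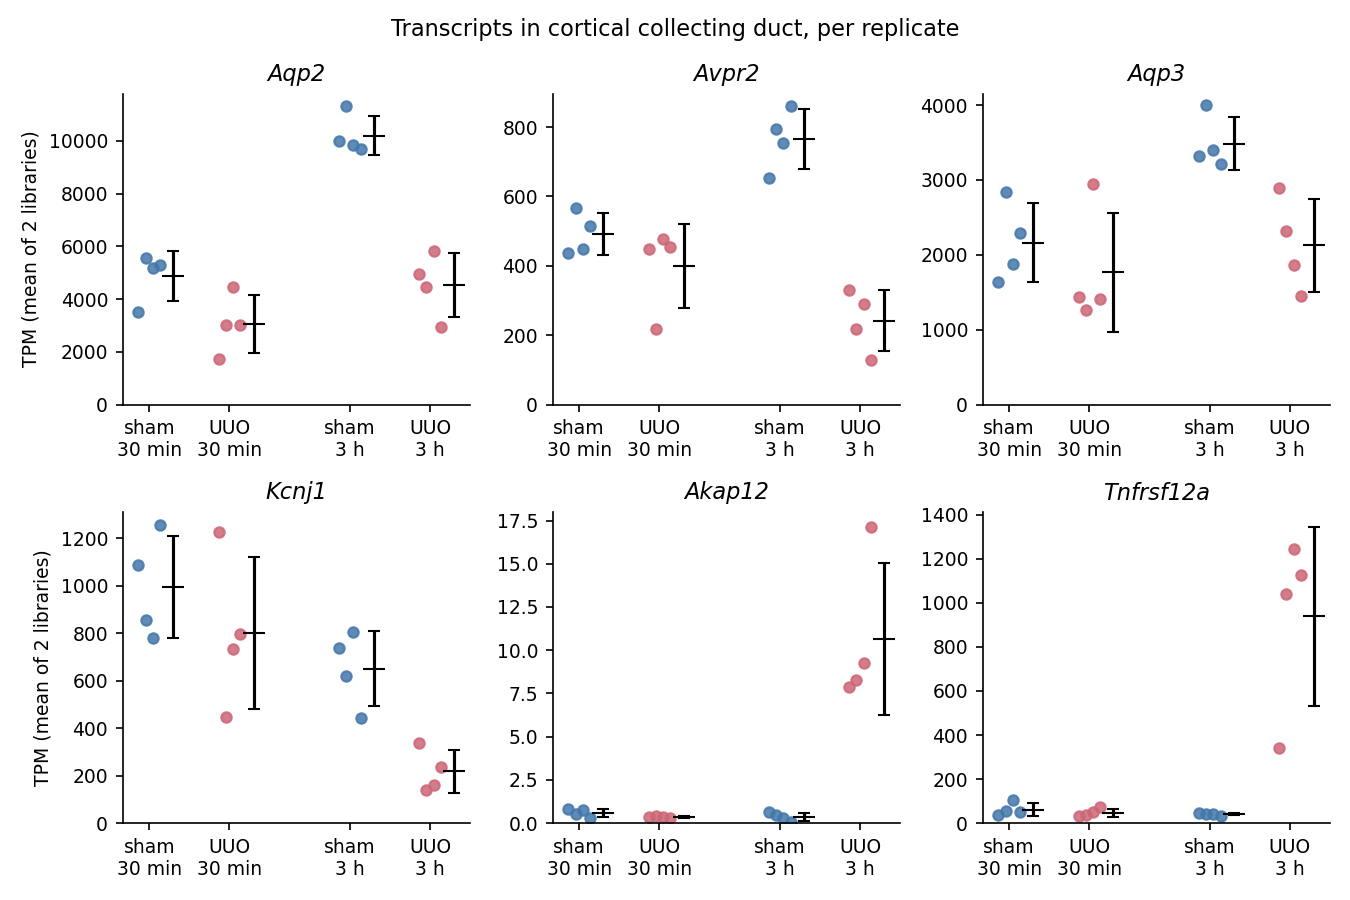
TPM of 6 transcripts in CCD, with 1 point per replicate (mean of its 2 libraries), sham in blue and UUO in red, and the mean ± SD of 4 replicates as bars. The 2 times come from separate tables and are not compared in level; at 3 h all UUO replicates lay below all sham replicates for Aqp2, Avpr2, Aqp3 and Kcnj1 and above them for Akap12 and Tnfrsf12a.

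After 3 h of obstruction Aqp2 and the vasopressin receptor Avpr2 had fallen in CCD. Aqp2 was 2.37-fold lower, at 4534 ± 1207 TPM in UUO against 10204 ± 754 TPM in sham (log2 change -1.24, SE 0.19, adjusted p = 0.00782), and all 4 UUO replicates lay below all 4 sham replicates. Avpr2 fell further, 3.40-fold, from 765 ± 86.5 to 242 ± 88.3 TPM (SE 0.27 on the log2 scale, adjusted p = 0.00762). At the same time some chemokines and injury markers rose, led by the chemokine Ccl20, which went from 3.73 ± 4.74 to 497 ± 362 TPM (98.5-fold, log2 SE 0.86, adjusted p = 0.00424). Tnfrsf12a, the receptor for the cytokine TWEAK, rose 20.7-fold from 40.3 ± 5.41 to 938 ± 408 TPM (log2 SE 0.36, adjusted p = 0.00124).

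In the principal cell transport list, 7 of 15 measured members fell, 1 rose and 7 were not called, and adjusted over the list alone 8 fell and 2 rose. Besides Aqp2 and Avpr2 the falls were Aqp3 (1.71-fold, a call lost in 6 of 8 fits without 1 replicate), the potassium channel Kcnj1 (3.12-fold), the mineralocorticoid receptor Nr3c2 (3.07-fold), and Scnn1b and Scnn1g, both subunits of the epithelial sodium channel (log2 change -0.73 each, the call of Scnn1b lost in 5 of 8 such fits). For Scnn1g (adjusted p = 0.0433) such losses were not counted. The riser was Akap12, a scaffold that binds protein kinase A, which went up 7.81-fold (adjusted p = 0.00124). As a whole this list was not called (adjusted p = 0.133, and adjusted p = 0.580 with an estimated correlation). The basolateral channel Aqp4, with a log2 change of -0.01 (SE 0.33), was not called, and Hsd11b2, at -0.98, and Fxyd4, at -0.64, did not pass (adjusted p = 0.0639 and 0.147). The 8 principal cell markers, all of which also belong to the transport list, were lower as a group, with 5 called, 7 called adjusted over the list alone, and adjusted p = 0.00189 (adjusted p = 0.334 with an estimated correlation). The two-sided exact permutation p was 0.0286, the smallest possible here, for Aqp2, Aqp3 and Avpr2 alike.

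Few of the factors described as regulators of Aqp2 were called, in a comparison where 14% of simulated changes of 0.5 were recovered. Of 17 measured members 1 was higher, 1 lower and 15 not called (1 higher and 3 lower adjusted over the list alone), and the list was not called (adjusted p = 0.733). Elf3, an epithelial ETS factor, rose 2.30-fold, and the homeobox factor Hoxb7 fell 1.88-fold. Gata3 had a log2 change of -0.62 and did not pass (adjusted p = 0.0533). Of 16 intercalated cell transport genes 1 was lower, the ammonia transporter Rhbg (1.48-fold, lost in 5 of 8 fits without 1 replicate), and 15 not called (1 lower adjusted over the list alone, adjusted p = 0.333 by camera). The anion exchanger Slc4a1 of type A cells had a log2 change of -0.59 that did not pass. The median over the 9 type A and type B intercalated cell markers was -0.07, while that over the principal cell markers was -0.75, and the rescaled medians were 0.07 and -0.61 with median-of-ratios.

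Inflammatory signalling genes were among those that rose in CCD at 3 h. Of 14 measured cytokines and chemokines 8 rose and 6 were not called (10 rose adjusted over the list alone), among them the neutrophil attractant Cxcl1 (25.3-fold), the monocyte attractant Ccl2 (9.83-fold) and the granulocyte growth factor Csf3 (9.74-fold), whose arms overlapped and whose call was lost in 7 of 8 fits without 1 replicate. In the NF-kB list 9 of 21 rose and 12 were not called (10 higher and 1 lower adjusted over the list alone), including the adhesion molecule Icam1 (7.38-fold), the inhibitor of apoptosis Birc3 (5.93-fold), the factor Irf1 (5.02-fold) and the inhibitor Nfkbia (2.34-fold). Socs3, which restrains cytokine receptors, rose 22.4-fold (adjusted p = 0.00219). Injury markers had 14 of 21 higher and 7 not called (15 adjusted over the list alone), such as keratin Krt19 (10.3-fold), the secreted siderophore-binding protein Lcn2 (10.2-fold) and the urokinase receptor Plaur (6.99-fold). Camera called all 3 lists as higher at the preset correlation (adjusted p = 2.25e-09, 2.77e-08 and 7.95e-14), but with an estimated correlation the cytokines had adjusted p = 0.0716, the NF-kB list adjusted p = 0.0989 and the injury markers adjusted p = 0.0716.

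Growth and immediate early genes gave a mixed picture. Of 19 immediate early genes 7 rose and 12 were not called, the same numbers as adjusted over the list alone, with the growth factor gene regulator Myc at 7.33-fold and Klf10 at 2.37-fold. Among 5 AP-1 factors Atf3 (5.74-fold, with arms that overlapped and a call lost in 6 of 8 fits without 1 replicate) and Mafk (2.41-fold) rose and 3 were not called, while Fos had a log2 change of 0.54, Jun -0.18 and the related Egr1 -0.06, none of which passed. Feedback inhibitors of MAP kinase and EGF receptor signalling rose in 4 of 10 cases (5 higher and 1 lower adjusted over the list alone), among them Dusp6 (4.54-fold, lost in 5 of 8 fits without 1 replicate), Errfi1 (4.50-fold) and Gadd45b (4.23-fold). The EGF receptor ligand Hbegf rose 7.04-fold, 1 of 2 called as higher among 6 EGF family genes (2 higher and 1 lower adjusted over the list alone), a list that was not called (adjusted p = 0.307). Camera called the AP-1, immediate early and feedback lists (adjusted p = 0.0211, 4.26e-04 and 7.91e-06), and the values with an estimated correlation were adjusted p = 0.280, 0.241 and 0.0716.

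NRF2 targets, and some genes of cell contacts, rose as well. Of 13 NRF2 targets 8 rose, 1 fell and 4 were not called, both over all genes and adjusted over the list alone, with Osgin1 (5.25-fold) and the metal-binding proteins Mt2A (3.94-fold) and Mt1 (3.70-fold) among them. The tight junction claudins Cldn4, from 90.2 ± 22.3 to 499 ± 214 TPM (5.06-fold), and Cldn3 (2.47-fold) led the junction list, in which 4 of 15 rose, 1 fell and 10 were not called (6 higher and 2 lower adjusted over the list alone). Among 11 YAP targets the matricellular proteins Ccn2 (5.58-fold) and Ccn1 (3.37-fold) rose with 1 other, 1 fell and 7 were not called (4 higher and 1 lower adjusted over the list alone), and the list's median of -0.02 and mean of 0.41 differed in sign. Of 19 cytoskeleton genes 3 rose, with the focal adhesion protein Zyx at 2.14-fold, and 16 were not called (3 higher and 1 lower adjusted over the list alone). Camera called all 4 of these lists as higher (adjusted p = 1.86e-07, 0.00364, 0.0184 and 0.00153), against adjusted p = 0.0716, 0.0716, 0.105 and 0.180 with an estimated correlation. The ribosomal proteins, with a median of 0.05 and 0 of 24 called, were also called by camera (adjusted p = 0.0267, and adjusted p = 0.580 with an estimated correlation). Heat shock proteins split, with 3 of 14 higher, such as Hspa1b (2.82-fold), and Hsph1 lower (log2 change -1.08), counts that did not change adjusted over the list alone, and the list was not called (adjusted p = 0.128). The unfolded protein and integrated stress response list, with 2 of 19 higher and 2 lower (3 higher and 4 lower adjusted over the list alone), was not called either (adjusted p = 0.333).

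Transcripts of some other cells were on average higher in the obstructed CCD samples in which these genes rose. Endothelial markers were not, with sums of 53.3 ± 9.35 TPM in UUO and 87.8 ± 45.5 TPM in sham. Proximal tubule markers summed to 727 ± 387 TPM in UUO and 145 ± 92.8 TPM in sham, with the gluconeogenic enzyme Fbp1 at 4.63-fold and the inositol enzyme Miox at 4.75-fold, calls lost in 5 and 6 of 8 fits without 1 replicate. Of 7 measured 4 rose, and 7 rose adjusted over the list alone (adjusted p = 1.17e-05, and adjusted p = 0.200 with an estimated correlation). Red blood cell markers summed to 3890 ± 2079 TPM against 458 ± 449 TPM, and all 3 measured rose, namely Hbb (31.1-fold), the haem synthesis enzyme Alas2 (4.62-fold) and a locus of Hba-a2 (log2 change 5.04), whose reads cannot be told from those of a second locus with certainty (adjusted p = 3.20e-04, and adjusted p = 0.200 with an estimated correlation). The complement genes C1qb (3.47-fold), C1qc (2.85-fold) and C1qa (2.01-fold) rose among 7 macrophage markers (adjusted p = 0.00189, and adjusted p = 0.200 with an estimated correlation). The smooth muscle marker Tagln rose 8.13-fold, and the connecting tubule protease Klk1 rose 2.67-fold in a list of 3 (adjusted p = 0.0486, and adjusted p = 0.334 with an estimated correlation). Umod and Slc12a1, markers of the thick ascending limb, had log2 changes of -1.07 and -0.17 that did not pass.

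In total limma called 1373 of 10530 genes in CCD at 3 h, 526 higher and 847 lower. Among all genes tested 20.9% had no overlap between the arms, where chance gives 2.86%. The 10 largest falls with no overlap were small nuclear RNA loci and a clone name, namely 1 copy of U4 (21.2-fold, lost in 5 of 8 fits without 1 replicate) and 8 copies of U1 with identical values (10.4-fold), which are near-identical genes among which reads cannot be placed with certainty. The median of all genes was -0.14, and median-of-ratios rescaling gave 700 higher and 455 lower, quantile normalization 636 higher and 660 lower, with Aqp2 at -1.09 and -1.21. A further fit left out the 5 UUO libraries above 50 TPM of the proximal tubule transporter Slc34a1. That limit was set after the data were seen. The fit called 757 genes, 216 higher and 541 lower. Its Aqp2 change was -0.84 with exact permutation p = 0.0667, the smallest p possible with only 2 UUO replicates left. Leaving out 1 replicate gave 460 called genes without sham replicate 2 and 1638 without UUO replicate 1, and leaving out the 3 replicates with a library above 5000 TPM of Umod gave 59. Leaving out only those 3 libraries, with every replicate kept, gave 1068 called genes (465 higher, 603 lower) and an Aqp2 change of -1.16.

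**Figure D2:**
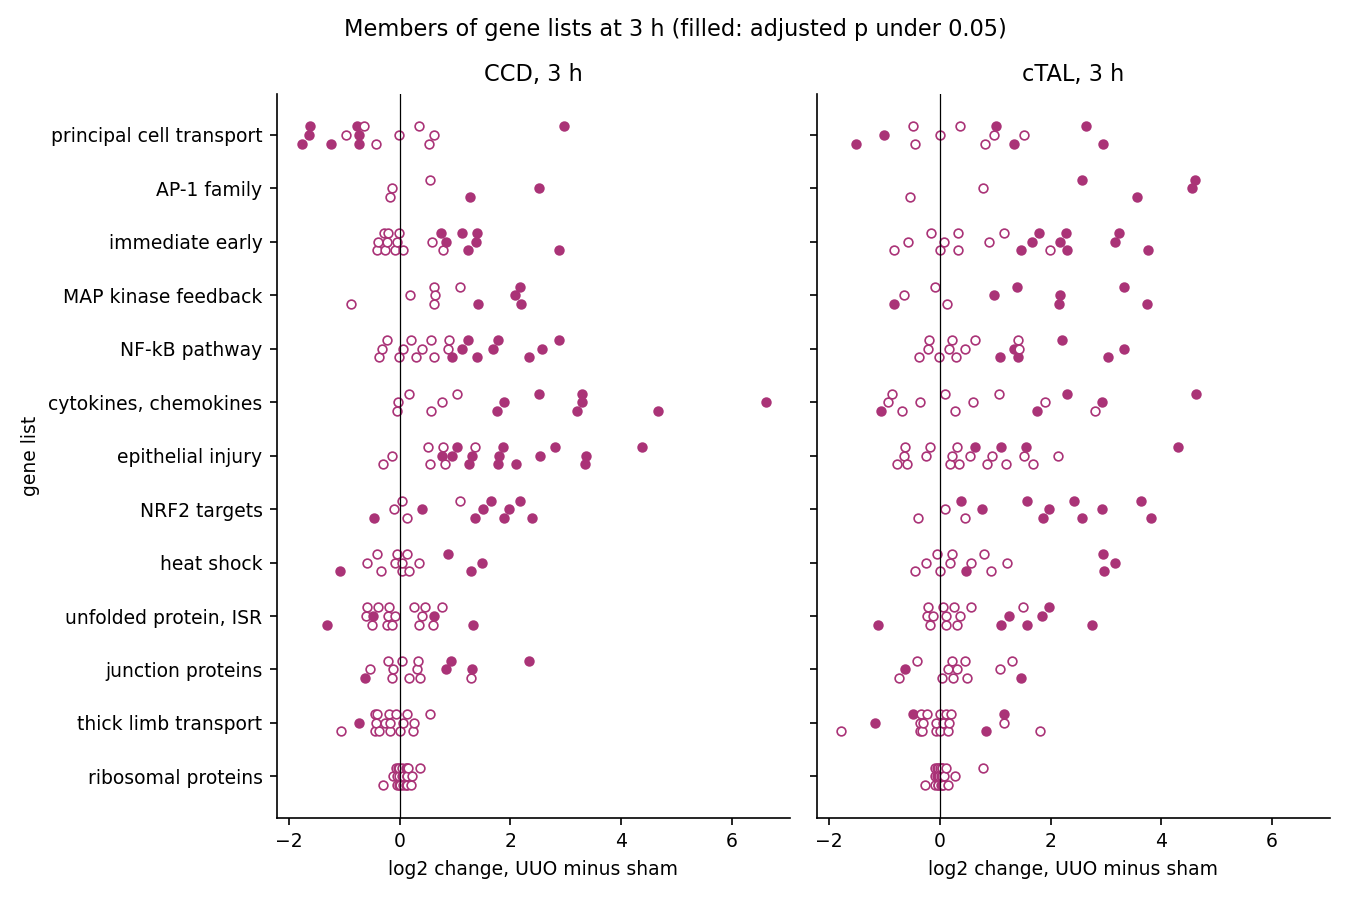
Log2 change, UUO minus sham, of each measured member of 13 gene lists in CCD (left) and cTAL (right) at 3 h, with 1 circle per gene, filled where the adjusted p was under 0.05. Injury and cytokine genes lie mostly to the right of 0 in CCD, NRF2 targets do so in both segments, and the ribosomal proteins lie close to 0.

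**Figure D3:**
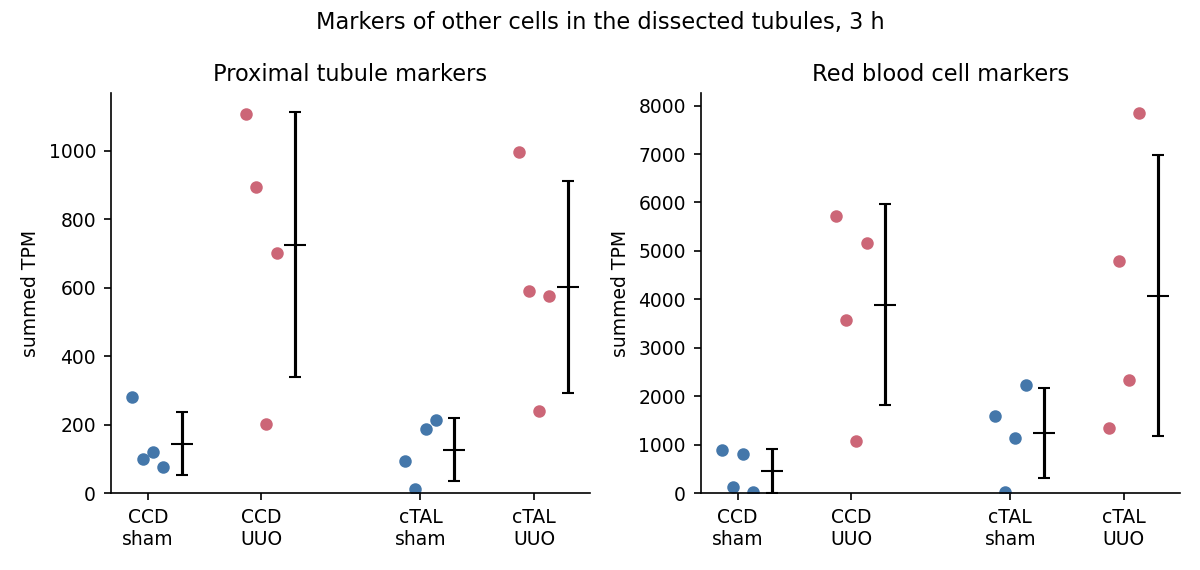
Summed TPM of proximal tubule markers (left) and red blood cell markers (right) in CCD and cTAL at 3 h, with 1 point per replicate and the mean ± SD of 4 replicates as bars. In CCD the proximal tubule sum was 145 ± 92.8 TPM in sham and 727 ± 387 TPM in UUO.

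The same question was asked of cTAL at 30 min, where no gene with a full name passed the test. Fos, an immediate early factor, was at 305 ± 163 TPM in UUO and 53.6 ± 27.7 TPM in sham (5.79-fold, log2 SE 0.46), Egr1 at 3.66-fold (log2 SE 0.57) and Atf3 at 4.30-fold (log2 SE 0.96), and none of the 3 was called, with adjusted p = 0.633 for Fos. Umod and Slc12a1 had log2 changes of -0.08 and -0.16 (SE 0.19 and 0.22). Some transcripts typical of CCD were at low levels but higher in UUO, while principal cell markers summed to 100.5 ± 18.9 TPM in UUO and 85.4 ± 25.1 TPM in sham. Aqp2 was at 7.39 ± 5.60 TPM against 0.678 ± 0.825 TPM and Aqp3 at 6.44 ± 5.86 TPM against 0.198 ± 0.116 TPM, and neither was called.

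Only AABR07007730.1 was called among 10993 genes in cTAL at 30 min, against 250 with an unadjusted p under 0.05. This locus, named after its values were seen, was listed at 0 in every sham library and stood at 21.2 ± 2.78 TPM in UUO (adjusted p = 6.50e-06). Among all genes 1.72% had no overlap between the arms, where chance gives 2.86%. The ammonia transporter Rhcg and the sodium channel subunit Scnn1g followed with log2 changes of 2.22 and 1.18, neither called (adjusted p = 0.318 each).

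As groups, the 6 AP-1 factors (median log2 change 1.00), the 21 other immediate early genes (0.35) and the 12 MAP kinase feedback genes (0.31) stood higher than other genes in cTAL at 30 min by camera (adjusted p = 1.71e-05, 5.79e-08 and 1.71e-05). All 3 had adjusted p = 0.251 with an estimated correlation, and 1 AP-1 gene was called adjusted over the list alone. Principal cell transport, intercalated cell transport, cytokines, NF-kB, TGF-beta and YAP lists were also called as higher, and mitochondrial metabolism as lower. Their values with an estimated correlation were adjusted p = 0.251, 0.223, 0.251, 0.575, 0.540 and 0.540 for the former and adjusted p = 0.540 for the latter. The NF-kB list had a median of -5e-04 and a mean of 0.09, which differ in sign. The principal cell markers were the 1 list that also passed with an estimated correlation (median 0.93 over 6 genes, adjusted p = 5.12e-13, and adjusted p = 0.00594 with an estimated correlation), with 3 higher adjusted over the list alone. The median level over the 8 matched principal cell markers was 5.70 TPM in cTAL UUO and 0.514 TPM in cTAL sham, against 711 TPM in CCD sham. Whether CCD RNA carried with the dissected tubules accounts for this rise was not tested. Markers of proximal tubule, connecting tubule and red blood cells were called as higher at the preset correlation, with adjusted p = 0.268, 0.164 and 0.116 with an estimated correlation.

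After 3 h of obstruction cTAL had changed broadly, with immediate early, oxidative stress and stress response genes among the largest rises. Atf3 rose 24.3-fold, from 1.08 ± 0.734 to 48.7 ± 16.8 TPM (log2 SE 0.36, adjusted p = 2.15e-04), and Fos 23.5-fold, from 8.54 ± 11.7 to 168 ± 120 TPM (log2 SE 0.70, adjusted p = 0.00515). The metallothionein Mt2A rose 14.1-fold, from 869 ± 278 to 11871 ± 1905 TPM (log2 SE 0.23, adjusted p = 2.72e-05). Nppc, which encodes C-type natriuretic peptide, rose 100.1-fold, from 0.158 ± 0.315 to 138 ± 88.8 TPM (log2 SE 0.50, adjusted p = 1.60e-04). Umod and Slc12a1, which define the segment, did not pass, with log2 changes of -0.35 and 0.05 (adjusted p = 0.174 and 0.930).

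Immediate early genes were among the rises in cTAL at 3 h. Of 6 AP-1 factors 4 rose and 2 were not called, with the same numbers adjusted over the list alone, namely Atf3, Fos, Junb (11.8-fold) and Jun (5.94-fold). Among 19 other immediate early genes 9 rose and 10 were not called (12 adjusted over the list alone), such as the antiproliferative Btg2 (13.6-fold), the mRNA decay factor Zfp36 (9.46-fold), Myc (8.98-fold) and Egr1 (4.89-fold). MAP kinase feedback genes rose in 6 of 10 cases, with Gadd45b at 13.3-fold and Errfi1 at a log2 change of 3.33, and 1 fell, with no difference adjusted over the list alone. The ligand Hbegf rose 10.7-fold (adjusted p = 2.28e-04), the 1 gene called of 5 EGF family genes, a list not called by camera (adjusted p = 0.0737) but called as higher by fry (adjusted p = 0.00511). Camera called the first 3 lists as higher (adjusted p = 6.18e-05, 3.65e-09 and 1.58e-04), against adjusted p = 0.0745, 0.0680 and 0.202 with an estimated correlation.

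Some stress genes rose in cTAL at 3 h, with the NRF2 targets ahead. Of 13 NRF2 targets 10 rose and 3 were not called, also adjusted over the list alone, with Mt1 (12.4-fold), Osgin1 (7.57-fold) and the glutathione synthesis enzyme Gclc (5.95-fold). This list passed at the preset correlation (adjusted p = 4.48e-10) and was the only pathway list in this comparison that passed with an estimated one (adjusted p = 0.00896). Among 19 genes of the unfolded protein and integrated stress response 6 rose, 1 fell and 12 were not called (8 higher and 1 lower adjusted over the list alone), with the glutathione-degrading Chac1 (6.69-fold), Trib3 (3.93-fold), Ppp1r15a (3.59-fold) and the factor Atf4 (log2 change 1.58). Of 14 heat shock proteins 4 rose and 10 were not called (5 adjusted over the list alone), such as Hspa1b (9.01-fold) and the small chaperone Cryab (7.78-fold). The p53 list had 1 of 8 higher, the cell cycle inhibitor Cdkn1a (3.45-fold), with 3 higher and 1 lower adjusted over the list alone. Camera called the latter 3 lists as higher (adjusted p = 1.67e-04, 1.97e-04 and 0.00412), against adjusted p = 0.0788, 0.0680 and 0.0680 with an estimated correlation.

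Some inflammatory and injury genes rose in cTAL at 3 h. Of 17 NF-kB genes 6 rose and 11 were not called (8 adjusted over the list alone), such as Birc3 (log2 change 3.32), Icam1 (8.19-fold) and Nfkbia (2.53-fold). Cytokines and chemokines rose in 4 of 15 cases, with Ccl20 (24.7-fold), Cxcl1 (7.63-fold) and Ccl2 (4.91-fold, lost in 6 of 8 fits without 1 replicate), and 1 fell (5 higher and 2 lower adjusted over the list alone). Of 21 injury markers 4 rose and 17 were not called (8 adjusted over the list alone), with Tnfrsf12a at 19.8-fold (adjusted p = 2.72e-05) and keratin Krt18 at 2.96-fold, while Lcn2 did not pass (log2 change 2.14, adjusted p = 0.131). Socs3 rose 21.1-fold, the YAP target Ccn2 5.98-fold in a list with 3 of 10 higher, and the cytoskeletal Zyx 3.15-fold in a list with 3 of 18 higher, the same counts as adjusted over each list alone. Camera called the NF-kB, cytokine, injury, YAP and cytoskeleton lists as higher (adjusted p = 2.11e-05, 0.0119, 7.29e-05, 0.00387 and 0.0286). With an estimated correlation they had adjusted p = 0.0680, 0.291, 0.0680, 0.0680 and 0.270.

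Among transport genes of cTAL the vasopressin receptor Avpr2 fell 2.84-fold, from 66.4 ± 2.14 to 23.0 ± 3.74 TPM (log2 SE 0.16, adjusted p = 0.00113). The thick ascending limb list was balanced, with 2 of 22 higher, 2 lower and 18 not called (2 higher and 4 lower adjusted over the list alone, adjusted p = 0.870). The sodium pump subunit Atp1b1 rose 2.23-fold, and the calcium-sensing receptor Casr and the claudin Cldn10 fell (log2 change -1.18 and -0.49). In the principal cell transport list, whose members are mostly low here, the aldosterone-induced kinase Sgk1 (6.25-fold) and Akap12 (7.70-fold) were among 4 of 13 that rose, and 2 fell (the same adjusted over the list alone, adjusted p = 0.112). Of the factors tied to Aqp2, 3 of 13 rose and 1, Tfap2b (2.96-fold), fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.266). The junction list had 1 of 13 higher, Cldn3 (2.77-fold), and 1 lower, Cldn8 (1.55-fold), with 2 higher and 1 lower adjusted over the list alone, and was not called (adjusted p = 0.0952). The other largest rises were the lipase inhibitor Angptl4 (70.9-fold), the cell cycle adaptor Sfn (25.7-fold) and Spp2 (20.4-fold).

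The largest falls in cTAL at 3 h with a full name were Cd200 (17.5-fold), Lgals9 (9.54-fold), Lrrc66 (9.08-fold), Fam167b (8.54-fold), Rgs18 (6.39-fold), Tmem255b (6.28-fold), Plek (6.17-fold), the endothelial lipase Lipg (6.01-fold) and Clec4a3 (5.82-fold). Of 4 measured endothelial markers 3 fell, also adjusted over the list alone, including Emcn and Cdh5 (log2 change -1.76 and -1.69, the call of Emcn lost in 6 of 8 fits without 1 replicate). Of 7 macrophage markers 2 fell, Csf1r and Cd68 (log2 change -1.68 and -1.58, the call of Cd68 lost in 7 of 8), with 3 lower adjusted over the list alone. Camera gave adjusted p = 0.0480 for each list, and with an estimated correlation adjusted p = 0.382 and 0.437. Endothelial markers summed to 65.6 ± 17.6 TPM in UUO and 203 ± 132 TPM in sham. Macrophage markers summed to 1573 ± 425 and 2205 ± 452 TPM. Whether a lower content of these cells accounts for other falls in cTAL was not tested. Proximal tubule markers were higher in the same UUO samples, summing to 601 ± 310 TPM against 127 ± 92.1 TPM in sham, with the glucose transporter Slc5a2 at 9.08-fold (lost in 6 of 8) and the anion transporter Slc22a6 at 6.18-fold. Of 7 measured 4 rose, and 7 rose adjusted over the list alone (adjusted p = 8.00e-06, and adjusted p = 0.382 with an estimated correlation). Red blood cell markers summed to 4078 ± 2905 TPM against 1240 ± 932 TPM, with 0 of 3 called (adjusted p = 0.0480, and adjusted p = 0.382 with an estimated correlation).

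In total limma called 1173 of 10023 genes in cTAL at 3 h, 407 higher and 766 lower, and 19.8% of all genes had no overlap between the arms, where chance gives 2.86%. The median of all genes was -0.12, and median-of-ratios rescaling gave 492 higher and 414 lower, quantile normalization 465 higher and 597 lower. Leaving out 1 replicate gave 471 called genes without sham replicate 2 and 1036 without UUO replicate 1.

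**Figure D4:**
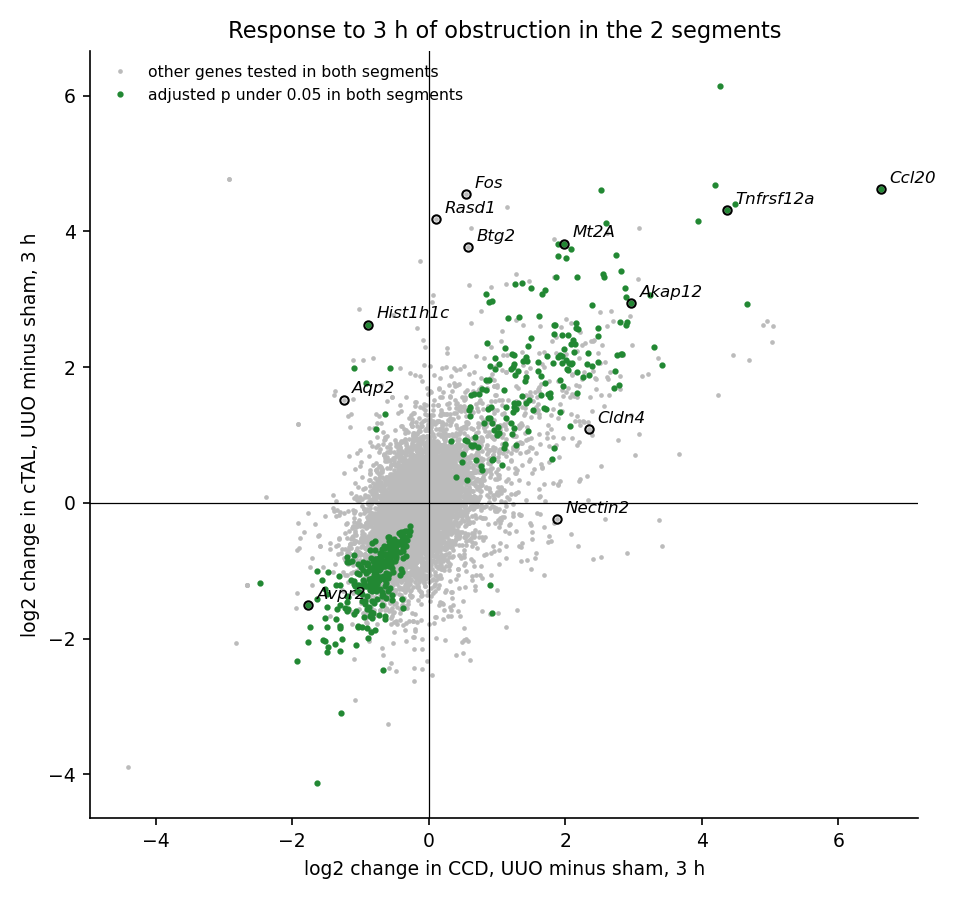
Log2 change at 3 h, UUO minus sham, in CCD (horizontal) and cTAL (vertical), with 1 point per gene tested in both segments and genes called in both in green. Tnfrsf12a, Ccl20 and Akap12 rose and Avpr2 fell in both, whereas Btg2, Rasd1 and Fos lie high for cTAL alone.

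The segments shared part of the 3 h response. Summed proximal tubule and red blood cell markers were also higher on average in UUO of both segments. Their part in this overlap was not tested. Across the 9469 genes tested in both, the log2 changes correlated with Pearson r = 0.594 and Spearman rho = 0.504, a relation across genes, which are not independent replicates. Because both segments of a number were taken to come from 1 animal, the same value was computed for the other splits of the 8 numbered animals, and those had a median of 0.342 and a highest value of 0.543. The covariance was 0.269, against a median of 0.0482 and a highest value of 0.130 over the other splits. Both segments called 176 genes as higher, of 491 in CCD and 381 in cTAL, where independent lists would share 19.8, and 251 as lower, of 782 and 712, where independent lists would share 58.8, and 8 were called in opposite directions. Tnfrsf12a, Ccl20, Socs3, Akap12 and Elf3 were among the shared rises and Avpr2 among the shared falls. At 30 min the correlation was 0.109, and the other splits had a median of 0.338 and a highest value of 0.664.

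Some genes responded differently in the 2 segments at 3 h, by the test of the difference itself. Hist1h1c, a linker histone gene, had a log2 change of -0.89 in CCD and 2.63 in cTAL (difference -3.52, SE 0.19, adjusted p = 3.78e-05). Rasd1, a Ras-related signalling protein, changed by 0.11 in CCD and 4.18 in cTAL, Igfbp1 by 0.62 and 4.04, Btg2 by 0.58 and 3.76, and H3f3a differed by -1.53. In the other direction, the adhesion protein Nectin2 changed by 1.89 in CCD and -0.24 in cTAL, the claudin Cldn4 by 2.34 and 1.08, RT1-S3 by 0.61 and -2.31, and Cfap20 and Mrpl36 differed by 1.42 and 1.17. In total 126 of 11084 genes were called, 65 with a more positive and 61 with a more negative change in CCD. Summed endothelial and macrophage markers were lower in UUO of cTAL at 3 h, and the part of such cells in these differences was not tested. Leaving out 1 replicate gave 17 called genes without UUO replicate 2 and 112 without UUO replicate 1.

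By group, cytokines and injury markers had more positive changes in CCD at 3 h, with median differences of 1.17 and 0.86 (adjusted p = 0.00128 and 1.36e-04, but adjusted p = 0.121 each with an estimated correlation). Members called were 0 higher and 1 lower of 16 cytokines and 2 higher of 22 injury markers, and adjusted over the list alone 4 higher and 1 lower, and 9 higher. More negative in CCD were principal cell transport (median -0.82, adjusted p = 1.60e-04), AP-1 (-2.42, adjusted p = 0.00590), other immediate early genes (-0.54, adjusted p = 9.86e-05) and the unfolded protein and integrated stress response (-0.69, adjusted p = 9.92e-05). Heat shock proteins, NRF2, hypoxia, prostaglandin and p53 lists were also more negative in CCD (adjusted p = 0.00128, 0.00181, 0.0165, 0.0165 and 0.00763). With an estimated correlation none of these 11 lists passed, and the lowest value was adjusted p = 0.101, for the immediate early genes, while fry called 10 of them, all but hypoxia. Macrophage and endothelial markers differed too, with median differences of 1.81 and 1.44 (adjusted p = 1.13e-04 and 0.00717), and both had adjusted p = 0.299 with an estimated correlation.

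At 30 min limma called 0 of 12075 genes for a difference between the segments, while 1792 had an unadjusted p under 0.05. The smallest adjusted p was 0.0573, shared by Hnrnpab, Mlycd, Ccng2 and Rnf215, with differences of -2.41, -1.39, -1.43 and -1.57. With all replicates the median of all genes was -0.23, and without UUO replicate 2 it was -0.11. Without UUO replicate 3 the count of called genes was 670. The lists called at the preset correlation were principal cell transport (median -0.54), immediate early genes (-0.84) and YAP targets (-0.56) as lower in CCD, and ribosomal proteins (0.14) as higher, and each had adjusted p = 0.870 with an estimated correlation. Fry called 0 of the 23 lists here. Principal cell markers were also lower (median -1.30, adjusted p = 0.0219, and adjusted p = 0.735 with an estimated correlation). That difference takes in the higher values of these markers in cTAL UUO, whose origin was not tested.

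The change from 30 min to 3 h was tested as the difference between the 2 responses. In CCD, Tnfrsf12a had a log2 change 4.72 higher at 3 h than at 30 min (SE 0.54, adjusted p = 9.34e-04), Ccl2 3.86, Akap12 3.19, Myc 2.97 and the tubulin Tubb6 2.45. More negative at 3 h were the proton pump subunits Atp6v1g2 and Atp6v0d1 (-1.50 and -1.13), the fatty acid binding protein Fabp3 (-0.99) and the tubulin Tuba8 (-1.62). In total 190 of 11696 genes were called, 160 more positive and 30 more negative at 3 h. The median of all genes was 0.19, and median-of-ratios rescaling gave 159 and 69, quantile normalization 120 and 121. Leaving out 1 replicate gave 35 called genes without sham replicate 2 of 30 min and 268 without UUO replicate 3 of 3 h.

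In cTAL, Nppc had a log2 change 6.86 higher at 3 h than at 30 min (SE 0.60, adjusted p = 2.79e-05), the uridine phosphorylase Upp1 3.56, Mt1 3.47, the LIM protein Csrp1 2.14 and the splicing factor Srsf3 1.51. More negative at 3 h were Lrrc66 (-3.09), Prmt2 (-1.80), Mrpl36 (-1.64), Avpr2 (-1.57) and Acot13 (-0.96). In total 271 of 11375 genes were called, 109 more positive and 162 more negative at 3 h, against 153 and 189 with median-of-ratios rescaling and 144 and 218 with quantile normalization. Leaving out 1 replicate gave 162 called genes without sham replicate 3 of 30 min and 344 without UUO replicate 1 of 3 h.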

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

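All tests of explanations in this part were chosen only after the result they explain was seen, except the test for a variant carried by some animals, which was written before its result was seen.

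Aqp2 and other principal cell transcripts were lower in CCD at 3 h, while proximal tubule and red blood cell transcripts were higher. A smaller share of principal cells would raise the 9 intercalated cell markers. The standard error of the mean over these markers, 0.135, takes them as independent and does not measure the spread between animals. Their median log2 change was -0.0746, 0.07 with median-of-ratios rescaling and -0.08 with quantile normalization. This was at first read as arguing against a smaller share, but the markers go both ways, from -0.99 for Hmx2 to 0.27 for Atp6v1g3, and the size of the rise to look for is unknown, so that explanation stays open. Dilution by RNA of other cells alone would lower intercalated markers as far as Aqp2, and their median lay 1.17 above it, which argues against dilution as the whole cause. Lower transcript levels within principal cells after obstruction may also account for the fall, alone or together with either, and cannot be told apart from a smaller share of these cells.

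The genes called as higher at 3 h rose in groups with higher mean sums of proximal tubule and red blood cell transcripts, although in CCD the proximal sum of UUO replicate 3, 202 TPM, lay below that of sham replicate 1, 281 TPM, and in cTAL the endothelial and macrophage sums were lower (65.6 against 203 TPM and 1573 against 2205 TPM). In CCD, without the 5 UUO libraries above 50 TPM of Slc34a1, the median log2 change of the 526 genes called as higher was 0.84 against 1.37 with all libraries, the lowest of 24 equally large sets of UUO libraries (SD 0.193, range 0.84 to 1.67), a value read as arguing against RNA of other cells until that spread was computed. In cTAL the median over the 407 genes called as higher was 1.45 in UUO replicate 3, lowest in proximal tubule markers, against 1.64 over all 4, and its proximal sum of 241 TPM lay above the highest sham sum of 214 TPM although its Slc34a1, 16.8 TPM, lay below that of sham replicate 4, 18.2 TPM. UUO replicate 1 had a red blood cell sum of 1341 TPM, within the sham range, and a median of 1.51, but the highest proximal sum of its group. RNA of other cells and a response of the tubule cells to obstruction cannot be told apart for these genes, as only 3 UUO libraries from 2 replicates remained in CCD and no UUO replicate of cTAL was as low as sham in summed proximal tubule markers.

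Locus AABR07007730.1 was at 18.46 to 43.66 TPM in the UUO libraries of both segments at 30 min and at most 0.7 TPM in sham, and at 3 h it reached 10 TPM in UUO replicate 4 alone (10.62 and 12.83 TPM in CCD, 14.46 TPM in cTAL). If the arms differed in processing or in the animals, other genes could be present in one arm and absent in the other, and 0 besides this locus were under 1 TPM in every library of one arm and at 5 TPM or more in every library of the other. These limits replaced an earlier pair, 0 TPM and 1 TPM, that no gene met, the called loci included, so a difference between the arms cannot be told apart from a response. A variant carried by some animals remains a candidate explanation, since 2 of the 3 loci called in CCD at 30 min were at 1 TPM or more in all 3 libraries of some 3 h animals and at 0 in all 3 libraries of others. AABR07051395.1, 1 of those 2, was detected in only some libraries of several animals, which lowers its weight, and no genome was at hand to check the sequence. Its animal with all 3 libraries positive was sham replicate 1, and those with none were UUO replicates. In CCD at 3 h it reached 24.12 TPM in sham and 3.77 TPM in UUO. RGD1560398 reached 16.89 TPM in sham and was at 0 in every UUO library there. Both thus kept their 30 min direction in CCD at 3 h, while in cTAL both were detected in both arms.

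Single replicates lay far from the other 3 of their group in 21 of 282 groups tested, and chance gives about 5%, so single cases carry little weight. In CCD at 30 min these were Aqp2 in sham replicate 1 (3494 TPM, others 5196 to 5556), Aqp3 in UUO replicate 3 (2948 TPM, others 1261 to 1443), Avpr2 in UUO replicate 2 (217 TPM, others 450 to 478) and Fos in sham replicate 1 (223 TPM, others 1124 to 1337). In CCD at 3 h UUO replicate 1 was low for Tnfrsf12a (339.74 TPM, others 1041 to 1244), Csf3 (0.735 TPM, others 32.4 to 49.8) and Tgif1 (19.3 TPM, others 42.7 to 47.4). UUO replicate 3 was high for Hspa1b (50.8 TPM, others 37.4 to 39.0) and low for Slc4a1 (17.8 TPM, others 26.7 to 28.8) and Errfi1 (24.2 TPM, others 51.9 to 59.5). UUO replicate 4 was low for Scnn1b (152 TPM, others 258 to 281) and high for Ccn1 (5.015 TPM, others 2.16 to 2.46) and Slc12a1 (63.8 TPM, others 1.27 to 2.67). Sham replicate 3 was low for Hoxb7 (247 TPM, others 295 to 300) and Egr1 (8.445 TPM, others 19.5 to 22.5), and sham replicate 4 for Nr3c2 (5.865 TPM, others 7.38 to 7.49). In cTAL at 3 h these were Akap12 in sham replicate 4 (0.02 TPM, others 0.76 to 0.80), Hbegf in sham replicate 3 (2.10 TPM, others 5.42 to 6.18), Btg2 in sham replicate 1 (19.2 TPM, others 11.8 to 12.8), Birc3 in UUO replicate 4 (40.7 TPM, others 11.9 to 14.3) and Lcn2 in UUO replicate 1 (1.56 TPM, others 34.3 to 46.7).

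The response differed between segments for 126 genes at 3 h, and between times for 190 genes in CCD and 271 in cTAL, each by a test of the difference itself. At 3 h the log2 change was more positive in CCD than in cTAL for Nectin2 (2.13), Mrpl36 (1.17), Cfap20 (1.42), RT1-S3 (2.92) and Cldn4 (1.26). It was less so for Hist1h1c (-3.52), Btg2 (-3.19), H3f3a (-1.53), Igfbp1 (-3.42) and Rasd1 (-4.07). In CCD the change at 3 h exceeded that at 30 min for Akap12 (3.19), Tnfrsf12a (4.72), Myc (2.97), Ccl2 (3.86) and Tubb6 (2.45), and lay below it for Atp6v1g2 (-1.50), Atp6v0d1 (-1.13), Fabp3 (-0.99), Tuba8 (-1.62) and AABR07025051.4 (-2.39). In cTAL it exceeded that at 30 min for Upp1 (3.56), Nppc (6.86), Srsf3 (1.51), Csrp1 (2.14) and Mt1 (3.47), and lay below it for Mrpl36 (-1.64), Lrrc66 (-3.09), Prmt2 (-1.80), Avpr2 (-1.57) and Acot13 (-0.96).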

How the results depend on the processing

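The settings that leave out libraries or replicates by Umod or Slc34a1, join library 1 with rescaling, remove mitochondrially encoded genes or take UUO number 2 in CCD at 30 min from its library 1 were tests chosen only after the result was seen. The depth of the libraries is unknown, so its effect on genes with low values could not be measured. Where a count of called genes moved by more than 1.5 times the cause was not tested, except that leaving out samples or testing more genes lowers power by construction. In CCD at 30 min, where 3 genes were called, a 5 TPM filter, library 2 alone and all libraries with a within-number correlation gave 1 each, averaging TPM before the log gave 37, and library 1 alone gave 878 (6 higher, 872 lower). Library 1 alone with median-of-ratios rescaling, chosen after seeing the data, gave 796 (97 higher, 699 lower). In CCD at 3 h no filter gave 852 genes, a log2 change of at least 1 gave 562, a joint fit 855, library 1 alone 631 and library 2 alone 456, and 2 settings chosen after seeing the data gave 59 (without the 3 replicates with a Umod-rich library) and 757 (without Slc34a1-rich libraries). Without the Umod-rich libraries alone, every replicate kept, the count was 1068. In cTAL a joint fit gave 3 at 30 min and 2234 at 3 h, and at 3 h no filter gave 760 and a log2 change of at least 1 gave 778. For the difference between segments at 3 h a pseudocount of 0.1 gave 77 and no filter 20. For the time difference in CCD they gave 85 and 35, and a 5 TPM filter 126. A log2 change of at least 1 gave 2820 for identity at 30 min and 2164 at 3 h. With the number as a block, CCD at 3 h had 770 genes (390 higher, 380 lower), cTAL at 3 h 580 (252 higher, 328 lower) and the segment difference at 3 h 29 (9 and 20), and the counts of CCD and cTAL at 30 min and of the segment difference there did not move. The block was not run for time differences or identity. Own numbers correlated at 0.0941, 0.120, -0.218 and -0.162 in CCD at 3 h, at -0.113, -0.196, -0.233 and 0.179 in cTAL at 30 min and at -0.0256, 0.05, -0.105 and -0.116 in cTAL at 3 h, with 1 of 8 replicates in each matching its own number best, so only CCD at 30 min was read as paired.

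Without 1 replicate, counts ranged from 2 to 3 in CCD at 30 min, 460 to 1638 in CCD at 3 h, 1 to 1 in cTAL at 30 min, 471 to 1036 in cTAL at 3 h, 5277 to 6273 for identity at 30 min and 2842 to 3692 at 3 h. Replicates that moved a count by over 1.5 times were, in CCD at 3 h, sham 1 (779), sham 2 (460), sham 3 (713), sham 4 (667), UUO 2 (649) and UUO 4 (801). In cTAL at 3 h they were sham 1 (749), sham 2 (471), sham 3 (632), sham 4 (643) and UUO 4 (672). For the segment difference at 30 min the range was 0 to 670, with UUO 3 (670, of which 659 lower) and UUO 4 (1), and at 3 h it was 17 to 112, with sham 1 (63), sham 2 (47), sham 3 (75), sham 4 (76), UUO 2 (17) and UUO 3 (43). For the time difference in CCD the range was 35 to 268, with sham 2 (35), sham 3 (38), sham 4 (90) and UUO 1 (71) of 30 min and sham 2 (64), sham 3 (65), sham 4 (43), UUO 2 (72) and UUO 4 (69) of 3 h. In cTAL it was 162 to 344, with sham 2 (172) and sham 3 (162) of 30 min. Aqp2 in CCD at 3 h kept its direction throughout, from -1.38 to -1.03 without 1 replicate. It was -1.24 with the block, where exact permutation p was 0.125, the smallest sign flips allow. Without Slc34a1-rich libraries it was -0.84 (exact permutation p = 0.0667, the smallest possible with 2 UUO replicates against 4 sham). At 30 min it ranged from -1.02 to -0.50 without 1 replicate, and was -0.42 with median-of-ratios rescaling (exact permutation p = 0.371) and -1.03 with library 2 alone. With an estimated correlation the pathway lists called numbered 0 in CCD at both times, 0 in cTAL at 30 min, 1 in cTAL at 3 h and 0 for both segment differences. Fry called 0 pathway lists in CCD and cTAL at 30 min and for the segment difference there, while the principal cell markers in cTAL at 30 min passed both (adjusted p = 0.00594 and 0.0181), and median-of-ratios rescaling gave 1 pathway list in CCD at 30 min and 9 for that difference. At 3 h fry called 9 pathway lists in CCD, 12 in cTAL and 10 for the segment difference. Over all alternatives, those chosen later included, 0 named genes reversed a called direction, 506 calls were lost and 12 gained among named genes of CCD at 3 h, and 222 lost and 11 gained in cTAL at 3 h. Of 97 named genes called in CCD at 3 h 57 stayed called without any 1 replicate and 10 under every alternative, and of 89 in cTAL 57 and 54 did so. Calls of named genes lost in most fits without 1 replicate are given as such beside their values, except for Scnn1g in CCD at 3 h, for which such losses were not counted.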

Other observations

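The tests of marker sums and of other splits of the replicates were chosen only after the results were seen. Several gene groups not described so far changed only in part at 3 h. In CCD, TGF-beta signalling and matrix genes had 2 of 14 higher, the repressor Tgif1 (3.59-fold) and the matrix protein Tgfbi (2.74-fold), also adjusted over the list alone (adjusted p = 0.0170, and adjusted p = 0.280 with an estimated correlation). Hypoxia and glycolysis genes split, with Angptl4 (19.3-fold) and Bnip3 (1.52-fold) higher and the glucose transporter Slc2a1 (1.74-fold) lower among 2 higher and 3 lower of 20, the same as adjusted over the list alone (adjusted p = 0.845). Prostaglandin synthesis had 2 of 10 lower, Ptgs1 (1.73-fold) and Ptges (1.34-fold), calls lost in 5 and 6 of 8 fits without 1 replicate, with 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.332 by camera, but called as lower by fry with adjusted p = 0.0496). The p53 list had 1 of 9 lower, Sesn1 (1.82-fold), thick ascending limb transport 1 of 18 lower, the chloride channel subunit Bsnd (1.67-fold), and mitochondrial metabolism 2 of 22 higher, the fatty acid oxidation enzymes Cpt1a and Acadl (log2 change 0.72 and 0.62, the call of Acadl lost in 5 of 8 such fits). These counts did not change when adjusted over the list alone, and none of these 3 lists was called (adjusted p = 0.333, 0.973 and 0.404).

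In cTAL at 3 h, hypoxia genes had 3 of 20 higher, Angptl4, Bnip3 (2.67-fold) and Ndrg1 (log2 change 1.09, lost in 6 of 8 fits without 1 replicate), with 5 higher adjusted over the list alone (adjusted p = 0.0550). Prostaglandin synthesis had 1 of 9 higher, the receptor Ptgfr (log2 change 1.35), and intercalated cell transport 1 of 11 lower, the proton pump subunit Atp6v1b1 (log2 change -0.73, lost in 6 of 8), both also adjusted over the list alone (adjusted p = 0.0952 and 0.835 by camera), and fry called the former as higher (adjusted p = 0.0477). TGF-beta, mitochondrial and ribosomal protein genes had 0 of 13, 0 of 21 and 0 of 24 called by limma, 0 adjusted over the list alone as well, and camera called none of the 3 (adjusted p = 0.197, 0.835 and 0.266). Of the markers of the segment's own cells, 1 of 8 thick ascending limb markers was lower, Cldn10, and as a list they were not called (adjusted p = 0.984). Principal cell markers had 1 of 6 lower, Avpr2, and were not called either (adjusted p = 0.984).

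Other marker lists were not called or were too small at 3 h. In CCD the thick ascending limb, type A and type B intercalated and endothelial markers had 0 of 6, 5, 4 and 3 called (adjusted p = 0.958, 0.724, 0.958 and 0.924). In cTAL the connecting tubule and type A intercalated markers had 0 of 3 each called (adjusted p = 0.0709 and 0.142). Distal convoluted tubule, fibroblast and smooth muscle markers had 1 or 2 genes measured, and apart from Tagln in CCD none was called over all genes, while the 2 fibroblast markers measured in CCD, Col3a1 and Dcn (log2 change 1.13 and 1.10), were higher adjusted over the list alone. Type B intercalated and lymphocyte markers had 1 gene measured in cTAL, not called. No podocyte or neutrophil marker passed the filter in either segment, and no lymphocyte marker did so in CCD.

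For some lists the median, the mean and the direction by camera did not share a sign. In CCD at 3 h the factors tied to Aqp2 had a median of -0.15 and a mean of -0.01 while camera's direction was up, and the EGF family had a median of -0.20 and a mean of 0.35. The unfolded protein and integrated stress response had -0.14 and 0.0013, and hypoxia genes -0.04 and 0.16. The thick ascending limb markers had a median of -0.30 with an upward direction, and the type B intercalated markers a median of 0.001 and a mean of -0.20. In cTAL at 3 h the pairs were -0.03 and 0.0057 for thick ascending limb transport, -0.06 and 0.06 for intercalated cell transport, and -0.07 and 0.05 for mitochondrial metabolism. Thick ascending limb markers had -0.07 and 0.16, and for principal cell markers camera's direction was down beside a median of 0.60.

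Some libraries stood apart by marker or coverage. In CCD at 3 h, Umod reached 18235 TPM in library 2 of UUO replicate 4, 6941 TPM in library 1 of sham replicate 1 and 7957 TPM in library 1 of sham replicate 3. The fewest genes at 1 TPM or more, 8744, were in library 2 of UUO replicate 2 in CCD at 30 min. The summed principal cell markers in CCD at 3 h were 16830 ± 1236 TPM in sham and 8427 ± 2009 TPM in UUO (two-sided exact permutation p = 0.0286, and 0.0571 adjusted over 8 such sums). The sum of proximal tubule markers gave exact permutation p = 0.0571 in CCD and 0.0286 in cTAL, and that of red blood cell markers 0.0286 and 0.114. The sum of thick ascending limb markers in cTAL was 45056 ± 11840 TPM in sham and 34826 ± 2073 TPM in UUO (exact permutation p = 0.0286). Adjusted over the 8 sums, these values became 0.0914 and 0.0571 for proximal tubule, 0.0571 and 0.152 for red blood cells and 0.0571 for thick ascending limb in cTAL, so no sum passed. As 0.0286 is the smallest exact p, a sum could pass only with most of the 8 at that value. The adjusted values therefore do not show that the arms are alike.

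The counts of called genes were set against all other ways of splitting the same replicates 4 against 4. In CCD at 3 h and in cTAL at 3 h, 1 of 35 splits, the real one, reached 1373 and 1173 genes, and the highest other split had 2 in each. For the difference between segments at 3 h the real split alone had 126 genes, 1 of 35, against 1. In CCD at 30 min 2 of 35 splits reached 3 genes, and among the 8 splits that part all 4 numbered pairs the real one had 3 and the highest other 1. In cTAL at 30 min 12 of 35 splits had as many as the real one, and the highest, 242, set sham 1, sham 2, UUO 1 and UUO 3 against the rest, which could reflect structure among the samples unrelated to obstruction. For the difference between segments at 30 min all 35 splits had at least 0 genes, the real count, and the highest had 2. For the time differences 1 of 100 splits reached 190 genes in CCD, the highest other having 78, and 2 of 100 reached 271 in cTAL, where the other split had 623. For segment identity 1 of 8 splits reached 6482 genes at 30 min and 1 of 8 reached 4121 at 3 h, too few splits to judge by. The correlation between segments at 30 min, 0.109, was reached in 30 of 35 splits (highest other 0.664), and that at 3 h, 0.594, in 1 of 35 (highest other 0.543). The real split alone reached its value for both segments at 3 h and for the segment difference and overlap there. That is the smallest share that 35 splits allow, in unadjusted checks chosen after the results, so chance is less likely there but not excluded. The splits for the time differences shuffled the arms within both times and ignored the numbered pairs. They thus ask about a response at either time, not a difference between times. Chance also remains open for cTAL, the segment difference and the overlap at 30 min. In CCD at 30 min it cannot be excluded over the 35 splits, and the 8 that part all pairs are too few. For the time difference in cTAL 2 of 100 is under 5%, but as another split called more genes than the real one, the count alone does not tie that difference to obstruction.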
